A study of Mus musculus with 15 samples.

How the data were processed

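RNA from CD4+CD25+ cells, a fraction rich in regulatory T (Treg) cells, was measured on 15 single-colour Affymetrix whole-transcript mouse arrays. The cells had been sorted from the spleens of wild-type (WT) mice and of mice lacking Ikzf2 (Helios), Ikzf4 (Eos) or both (dKO). Per the labels' protocols, 15 ng of total RNA per array was amplified with a NuGEN whole-transcript kit and labelled with biotin. The values deposited by the authors are log2 signals, made with Affymetrix Expression Console 1.3.1 and robust multi-array averaging (RMA) per the submitters' processing notes. RMA subtracts background, quantile-normalizes arrays processed together and summarises the probes of a probe set, which compresses the changes of dim genes. The table holds 35556 probe sets. No scanner files were used here, so neither background nor normalization was repeated from raw signals.

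The WT arrays are numbered 1 to 6 in the labels, and their numbering and place in the series put them in 2 sets. Set 1 holds WT 1 to 3, Ikzf4-/- and dKO (9 arrays), and set 2 holds WT 4 to 6 and Ikzf2-/- (6 arrays). This division was fixed, as an inference, before the data were examined, as were the comparisons, gene lists, naming rule and most alternatives. It was then checked in the values. Pairs of arrays within set 1 had exactly equal log2 values in 2286 probe sets on average, pairs within set 2 in 34.4, and pairs across sets in 0.0741, the pattern of 2 sets normalized separately. WT 4 to 6 differed from WT 1 to 3 in 6950 of 10834 genes (555 higher and 6395 lower, limma, adjusted p threshold 0.05), with a median log2 difference of -0.39. The balance of directions depends on the scaling: at equal array medians the median difference was 0.052, and more genes were higher than lower. That set difference correlated across genes with Ikzf2-/- minus the mean of Ikzf4-/- and dKO, which shares no array with it (Pearson r = 0.789; genes are not independent replicates). Each knockout was therefore compared with the WT arrays of its own set. A comparison of dKO with Ikzf2-/- is the difference of both within-set changes from WT.

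Probe sets were named through the platform's annotation table, with symbols updated through Entrez identifiers to GRCm38.p6. Of the probe sets, 21789 had 1 symbol (21698 of them updated), 1621 had several and 12146 were not listed. Only probe sets with 1 symbol were used for named genes. For a gene with several probe sets, the probe set with the highest mean was kept. A gene was tested if any group mean lay above the median of all probe set means (log2 4.96), which left 10834 genes. The number of arrays limits the precision. The genome build of the array design is not given in the sources used here, so no coordinates are printed, and the reference table served only for names and gene order.

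All 15 arrays entered a limma 3.58.1 fit in R 4.3.3 (lmFit and eBayes) with 5 cell means, WT being separate in each set, so that all groups shared an estimate of the spread (10 residual and 3.73 prior degrees of freedom). P-values were adjusted over all genes by Benjamini-Hochberg at 0.05. A total of 30 gene lists were written, of which 27 had at least 3 measured members; 356 of 462 listed genes were measured. Lists were tested with limma's camera at its preset correlation of 0.01 and adjusted over the lists, with an estimated correlation and fry's test of one direction as alternatives. Member counts are given adjusted over all genes and adjusted over the list alone. A list member is called here if it passed either adjustment. No label says that arrays came from separate animals, so p-values measure the spread between these arrays, which may be partly technical.

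The naming rule took Ikzf1 to Ikzf5, Foxp3, Il2ra, Ctla4 and Tnfrsf18 always, up to 10 genes per direction and comparison past the threshold, up to 4 further called members per list, and the 5 smallest p where no gene passed. Up to 3 members per list that did not pass are given as values. Genes named outside this rule are said to be so.

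Replicate numbers are shared between the groups of set 1. Deviations from group means correlated, for numbers 1, 2 and 3, at 0.135, 0.218 and 0.306 between WT and Ikzf4-/-, and at 0.430, 0.197 and 0.267 between Ikzf4-/- and dKO, so the numbers pair these arrays, on evidence from the values alone. Between WT and dKO they were 0.071, 0.046 and 0.172, which does not meet that criterion. In set 2 no numbers are shared. The arrays numbered 3 in set 1 had log2 signals of the Y-linked gene Eif2s3y between 8.17 and 8.81 and dKO 2 had 7.94, while the other 11 arrays lay between 2.87 and 3.09.

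The procedure was tested on simulated data for 10834 genes, with the spread of each gene pooled over the groups of a set. In the simulated dKO vs WT comparison, 47.8%, 94% and 100% of genes changed by log2 0.5, 1 and 2 were recovered, and 5.29% of calls were unchanged genes. In the simulated Ikzf2-/- vs WT comparison, recovery was 68.7%, 94% and 100%, but 40.3% of calls were unchanged genes. The simulated Ikzf2-/- arrays had the same spread as the WT arrays of their set, while limma used the spread shared by all groups. A separate spread for the Ikzf2-/- arrays was not simulated.

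Alternative settings were the WT arrays pooled or of the other set, only the groups compared, other filters, normalizations, probe set rules and variance models, array weights, the replicate number as a block, and each array left out in turn. Added after the data were seen were fits without the arrays WT 1 and Ikzf2-/- 3, fits with the B cell list mean or the Eif2s3y signal as a covariate, fry's test of change in either direction, the 9 arrays of set 1 alone, the correlation of Ikzf2-/- vs WT with dKO vs Ikzf4-/-, and its permutation within replicate pairs.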

Results

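Gene expression was profiled in splenic CD4+CD25+ T cells, which the labels name Treg cells, the cells that restrain immune responses under the transcription factor Foxp3. Helios, encoded by Ikzf2, and Eos, encoded by Ikzf4, are zinc finger proteins of the Ikaros family that Treg cells express. The series asks how loss of either factor, or of both, changes the transcriptome. It holds 6 WT arrays and 3 arrays each of Ikzf2-/-, Ikzf4-/- and dKO cells. Array medians of the log2 signal over all probe sets lay between 4.82 and 5.01.

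The targeted genes were examined first. The Ikzf2 probe set had a mean log2 signal of 9.47 ± 0.51 (SD, n = 3) in Ikzf2-/- cells against 10.33 ± 0.08 (SD, n = 3) in WT 4 to 6, a log2 change of -0.86 (SE 0.20) that did not pass limma's threshold (adjusted p = 0.0885). Without Ikzf2-/- 1 it passed (-1.15, adjusted p = 0.00454). The 3 Ikzf2-/- arrays read 10.06, 9.15 and 9.22. In dKO cells Ikzf2 was 10.29 ± 0.27 (SD, n = 3) against 10.65 ± 0.17 (SD, n = 3) in WT 1 to 3, a change of -0.37 (SE 0.20, adjusted p = 1). The array labelled dKO 3 read 10.59, within the range of the WT arrays of its set. Ikzf4 was not lower in any knockout: its log2 change was 0.21 (SE 0.10) in Ikzf4-/- and 0.15 (SE 0.10) in dKO. Where these probes lie relative to the deleted exons is not known here, and a probe outside the deleted part checks nothing, so these signals do not settle the labels.

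**Figure D1:**
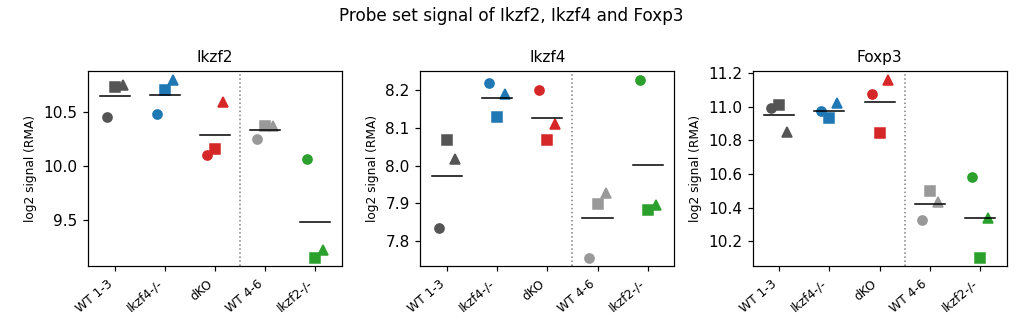
Log2 RMA signal of the Ikzf2, Ikzf4 and Foxp3 probe sets in each array by group, with circle, square and triangle in label order within a group, a bar at the group mean and a dotted line between the separately normalized sets. Ikzf2 reads 9.15 to 10.06 in the Ikzf2-/- arrays and 10.25 to 10.38 in WT 4 to 6, while Ikzf4 is no lower in Ikzf4-/- (mean 8.18) than in WT 1 to 3 (mean 7.97).

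Foxp3, Il2ra, Ctla4 and Tnfrsf18 did not pass the threshold in a single knockout or in dKO with all arrays. The log2 difference of Foxp3 from WT was -0.08 in Ikzf2-/-, 0.03 in Ikzf4-/- and 0.08 in dKO (SE 0.12). The corresponding values were -0.23, 0.01 and -0.01 for Il2ra, the high-affinity interleukin-2 receptor chain used for the sort (SE 0.12). They were 0.03, 0.09 and 0.20 for the inhibitory receptor gene Ctla4 (SE 0.09), and -0.04, 0.03 and 0.07 for Tnfrsf18, which encodes GITR (SE 0.18). Leaving out Ikzf2-/- 1 gave Il2ra an adjusted p of 0.0364 in limma, with a log2 difference of -0.39. Leaving out Ikzf2-/- 2 gave Foxp3, Il2ra, Ctla4 and Tnfrsf18 log2 differences of 0.04, -0.10, 0.11 and 0.26 in Ikzf2-/-, none of which passed. The list of 22 core Treg genes was not called in any of the 6 comparisons. Of its members only Socs2, a suppressor of cytokine signalling, passed in them adjusted over the list alone, with rises of 0.66 in Ikzf2-/-, 0.54 in dKO against WT and 0.47 in dKO against Ikzf4-/- (SE 0.12 for each). Of the other family members, Ikzf1 (Ikaros) stood at 0.04, 0.11 and 0.27 (SE 0.10), Ikzf3 (Aiolos) at 0.35, 0.09 and 0.29 (SE 0.13) and Ikzf5 at -0.42, -0.02 and 0.02 (SE 0.21) in Ikzf2-/-, Ikzf4-/- and dKO. None passed with all arrays, and Ikzf3 passed in Ikzf2-/- without Ikzf2-/- 2 (0.51, adjusted p = 0.0425).

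Loss of Ikzf2 alone was read from Ikzf2-/- against WT 4 to 6. Limma called 7 genes, 4 higher and 3 lower, with 1774 at an unadjusted p under 0.05. Ccr3, a chemokine receptor gene best known from eosinophils, rose 2.05-fold (log2 1.03, SE 0.17, adjusted p = 0.0428). Ticrr, a regulator of replication initiation, rose by 0.76 (SE 0.11), Map6, a microtubule-associated protein gene, by 0.65 (SE 0.10) and Prg4 (lubricin) by 0.64 (SE 0.10). Tbrg3 fell by 1.06 (SE 0.17), Thada fell by 0.77 (SE 0.12), and Wwp1, a ubiquitin ligase gene, fell by 0.58 (SE 0.09). Adjusted p was 0.0428 for all of them. Ikzf2-/- arrays varied more than the other groups (median gene SD 0.194, against 0.0922 to 0.110). Of the 15 arrays, Ikzf2-/- 2 had the lowest array weight (0.126, against 0.363 to 2.27), and within set 2 its core Treg list mean was 8.14, against 8.60 to 8.97, and its signal of Cd8b1, the 1 measured CD8 T cell gene, 7.31, against 6.06 to 6.12. Limma called 0 genes with only the groups compared, with all 6 WT arrays pooled, or with the B cell mean or the Eif2s3y signal as a covariate, and 2 without a filter, while quantile normalization and array weights gave 23 and 66. Without Ikzf2-/- 1, 2 or 3 the counts were 404, 165 and 2, without WT 1 the count was 3, and leaving out any of the other 11 arrays gave 0.

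Of 29 measured cell cycle genes, 13 rose in Ikzf2-/- cells adjusted over the list alone, 0 passed over all genes, and 16 did not pass. Ccnb2 (cyclin B2) rose by 1.38 (SE 0.33), Mki67, the Ki-67 antigen, by 1.08 (SE 0.32), Nusap1, a spindle protein gene, by 1.04 (SE 0.35) and Ccna2 (cyclin A2) by 0.99 (SE 0.35). The list's median change was 0.68, and camera called it (adjusted p = 4.85e-07), a call lost with an estimated correlation (adjusted p = 0.912) and in fry's test of one direction (0.407). Its mean over genes was 7.39 in Ikzf2-/- 3, the array with the highest B cell list mean (7.41), and 6.81 and 6.44 in Ikzf2-/- 1 and 2, against 6.15 to 6.41 in WT 4 to 6. Without Ikzf2-/- 3 the median was 0.34 and still called (adjusted p = 0.00449), and Nusap1 and Ccna2 stood at 0.62 and 0.65. Of 28 oxidative phosphorylation genes, 13 rose adjusted over the list alone and 0 over all genes. They included the complex I subunit genes Ndufb8 (0.46, SE 0.10), Ndufb5 (0.37, SE 0.11) and Ndufa1 (0.37, SE 0.11), and Uqcrfs1 of complex III (0.43, SE 0.10). The median change was 0.22 (camera adjusted p = 0.000186; adjusted p = 0.912 with an estimated correlation, and in fry 0.281 in one direction and 0.0225 in either), and with all 6 WT arrays pooled it was -0.058 and not called (adjusted p = 0.159), nor was it called with those of the other set (-0.26, adjusted p = 0.653).

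Of 22 genes of the activated/effector Treg list, 4 rose adjusted over the list alone and 0 over all genes. They were the suppressive cytokine gene Il10 (1.54, SE 0.48), the chemokine receptor genes Ccr2 (1.07, SE 0.32) and Cxcr3 (0.72, SE 0.19), and Fgl2 (1.04, SE 0.29), a secreted effector of Treg cells. The list median was 0.31 (camera adjusted p = 0.00955; adjusted p = 0.912 with an estimated correlation and 0.567 in fry's test of one direction). The call was also lost without WT 6 (adjusted p = 0.156), Ikzf2-/- 1 (0.380) or Ikzf2-/- 3 (0.0954), under the stricter filter (0.077), without both B cell arrays, WT 1 and Ikzf2-/- 3 (0.0805), and with the B cell mean as a covariate (0.158), while without Ikzf2-/- 2 the median was 0.545 and called (adjusted p = 0.000147). Adjusted over their lists alone, Socs2 (0.66, SE 0.12) and Ccnd2 (0.27, SE 0.07) of the interleukin-2/STAT5 targets rose too, as did the glycolysis gene Pgk1 (0.36, SE 0.09) and the ribosomal gene Rplp0 (0.38, SE 0.08), while camera did not call these lists. Fry's test of change in either direction, which does not compare a list with other genes, passed for the interleukin-2/STAT5, ribosomal and chemokine receptor and homing lists (adjusted p = 0.0406, 0.0429 and 0.0321).

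Markers of other cells were read beside these lists. In Ikzf2-/- the B cell list had a median change of 0.92 and the neutrophil list of 1.93, both called by camera (adjusted p = 0.00951 and 0.00669), and both calls were lost with an estimated correlation (adjusted p = 0.912 for each). Without Ikzf2-/- 3 the medians were 0.20 and 0.82 and neither was called (adjusted p = 0.600 and 0.0527), and without Ikzf2-/- 2 the B cell median was 1.55 and called (adjusted p = 0.000455). Of 13 B cell genes 0 passed adjusted over the list alone. Of 6 neutrophil genes only Camp, an antimicrobial peptide gene, rose adjusted over the list alone (1.88, SE 0.60; 0.85 without Ikzf2-/- 3), while S100a8 stood at 3.20 (SE 1.21). The B cell list mean was 7.41 in Ikzf2-/- 3, 5.61 in Ikzf2-/- 1 and 4.94 in Ikzf2-/- 2, against 5.03 to 5.22 in WT 4 to 6. The neutrophil list mean was 9.58, 7.24 and 6.56 in those Ikzf2-/- arrays, against 5.37 to 6.08. The B cell call was also lost under the stricter filter (adjusted p = 0.449). Its loss with the B cell mean as a covariate (0.941) was fixed in advance, as the covariate is this list's own mean. The neutrophil median was 0.82 with the B cell mean as a covariate (adjusted p = 0.0739). Camera did not call the remaining 22 lists.

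**Figure D2:**
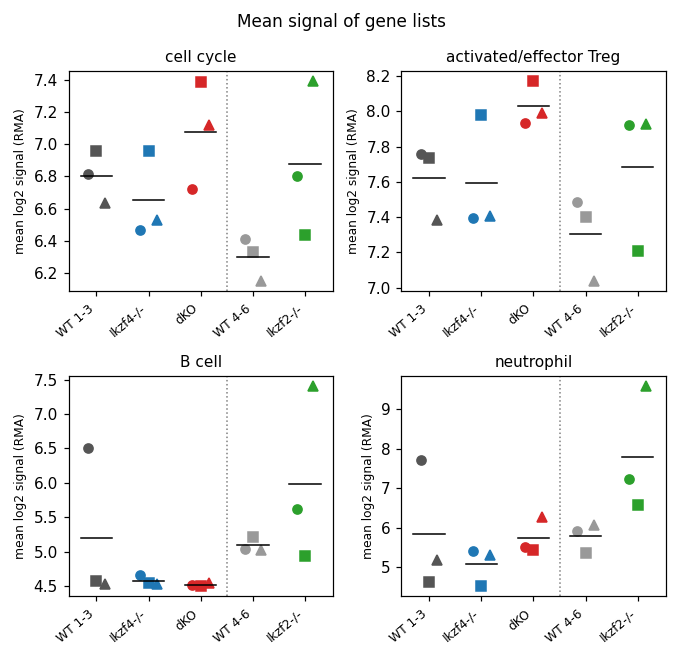
Mean log2 signal of the measured members of the cell cycle, activated/effector Treg, B cell and neutrophil lists in each array, with a bar at the group mean and a dotted line between the separately normalized sets. B cell and neutrophil means are highest in WT 1 within its set (6.51 and 7.71) and in Ikzf2-/- 3 (7.41 and 9.58), and the cell cycle mean reaches 7.39 in dKO 2.

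Loss of Ikzf4 alone was read from Ikzf4-/- against WT 1 to 3, and no gene passed. Limma called 0 of 10834 genes (smallest adjusted p = 1), with 233 at an unadjusted p under 0.05, which is 2.15%. That share is below the one unchanged genes would give at 0.05, so the test may be conservative here. The shared spread includes the Ikzf2-/- arrays (median gene SD 0.194, against 0.0922 in Ikzf4-/- and 0.102 in WT 1 to 3). With the replicate number as a block, fitted to set 1 alone, limma called 0 genes again, with 529 at an unadjusted p under 0.05. A count of 0 therefore does not show that nothing changed. The 5 smallest p belonged to Ntn4 (netrin 4, -1.21, SE 0.24), the ceramidase gene Acer2 (0.67, SE 0.14), Hddc3 (0.63, SE 0.13), the interferon-induced gene Oasl2 (-0.85, SE 0.20) and the deubiquitinase gene Yod1 (0.43, SE 0.10), none of which passed over all genes. Without WT 2, limma called 1 gene, Acer2 (0.87, adjusted p = 0.0216).

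Camera called 4 lists in Ikzf4-/-, and none of these calls held in fry's test of one direction (adjusted p = 0.963 for each) or of either direction, which passed for 0 lists. Cholesterol synthesis genes had a median change of 0.14, with 14 of 15 members positive (adjusted p = 0.000351, and adjusted p = 0.976 with an estimated correlation), and Idi1 (0.46, SE 0.20) and Cyp51 (0.43, SE 0.13) had the largest values, which did not pass. Interferon response genes had a median of -0.16, with 18 of 22 negative (adjusted p = 0.000412, and adjusted p = 0.976 with an estimated correlation), and only Oasl2 fell adjusted over the list alone. Cell cycle genes had a median of -0.14, with 23 of 29 negative (adjusted p = 0.00119, and adjusted p = 0.976 with an estimated correlation). With the B cell mean as a covariate the cell cycle median was -0.021 and the interferon median -0.064, neither of them called (adjusted p = 0.496 and 0.139), while without WT 1, the array with the highest B cell mean of the set, they were -0.16 and -0.20 and both were called (adjusted p = 0.0128 and 0.00144). The cell cycle call was lost without WT 2 (adjusted p = 0.165), Ikzf4-/- 1 (0.372) or Ikzf4-/- 3 (0.0986), and the interferon call without WT 2 (0.136) or Ikzf4-/- 1 (0.151). The B cell list had a median of -0.63 (adjusted p = 0.000351, and adjusted p = 0.976 with an estimated correlation), which was 0.01 without WT 1. The list mean was 6.51 in WT 1, against 4.53 to 4.66 in WT 2, WT 3 and the Ikzf4-/- arrays. The call was also lost under the stricter filter (adjusted p = 0.0619). Its loss with the B cell covariate (0.784) was fixed in advance, as the covariate is this list's own mean. With the WT arrays of the other set the cell cycle and cholesterol calls were lost (adjusted p = 0.199 and 0.0912). The neutrophil list had a median of -0.94, with 6 of 6 negative, and the macrophage and dendritic cell list of -0.13, with 6 of 7 negative, neither of them called (adjusted p = 0.0679 and 0.124). Their means were also highest in WT 1 (7.71 and 7.86, against 4.52 to 5.42 and 6.82 to 7.48 in WT 2, WT 3 and Ikzf4-/-). Medians of calls that held moved to -0.24 without WT 3 and -0.30 without Ikzf4-/- 2 for the cell cycle, to -0.96 without WT 2 for the B cell list and to 0.082 without Ikzf4-/- 3 for cholesterol synthesis. Without Ikzf4-/- 1, 2 lists were called.

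Loss of both factors was read from dKO against WT 1 to 3. Limma called 7 genes, 3 higher and 4 lower, with 468 at an unadjusted p under 0.05. It called 1 with only the compared groups, 2 when quantile-normalized again, 0 without a filter and 0 with the Eif2s3y signal as a covariate, a Y-linked signal present in dKO 2, the array labelled dKO 3 and WT 3. Csf1, which encodes the macrophage growth factor M-CSF, rose 2.17-fold (log2 1.12, SE 0.16, adjusted p = 0.0399). Tnfsf8, the CD30 ligand gene, rose by 0.98 (SE 0.15) and Gpm6b, a membrane glycoprotein gene, by 0.96 (SE 0.15). Acadl, the mitochondrial long-chain acyl-CoA dehydrogenase gene, fell to 0.322 of the WT level (log2 -1.64, SE 0.26). Hdac9, a histone deacetylase gene, fell by 0.93 (SE 0.14) and Islr fell by 0.84 (SE 0.13), all with an adjusted p of 0.0399. Il18r1, a chain of the interleukin-18 receptor, fell by 0.77 (SE 0.12, adjusted p = 0.0438). Leaving out WT 4, Ikzf2-/- 2 or Ikzf2-/- 3 gave 5, 9 and 8 genes, leaving out WT 6 gave 4, and leaving out any of the other arrays gave 0 or 1.

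Camera called 5 lists in dKO against WT: the activated/effector Treg, chemokine receptor and homing, cell cycle and effector cytokine lists, with positive medians, and the B cell list, with a negative one. None of these calls held in fry's test of one direction (adjusted p = 0.908 for each), and its test of either direction passed for the chemokine receptor and homing list alone (adjusted p = 0.0221). Of 22 activated/effector Treg genes, 20 were positive, and 4 rose adjusted over the list alone (0 over all genes). These were Ccr2 (1.51, SE 0.32), the inhibitory receptor gene Lag3 (0.73, SE 0.23), Cxcr3 (0.59, SE 0.19) and the transcription factor gene Maf (0.51, SE 0.12). The median was 0.34 (camera adjusted p = 9.52e-07; adjusted p = 0.79 with an estimated correlation). Il10 stood at 1.13 (SE 0.48) and Gzmb at 1.05 (SE 0.54), which did not pass. Of 22 chemokine receptor and homing genes, 5 rose adjusted over the list alone, among them Ccr3 (0.79, SE 0.17) and Gpr15, a receptor that guides T cells to the colon (0.76, SE 0.21). Their list had a median of 0.17 (camera adjusted p = 0.00105, and adjusted p = 0.79 with an estimated correlation). It shares Ccr2 and Cxcr3 with the activated/effector list. Adjusted over their lists alone, Slamf6 (0.45, SE 0.09) and Socs2 (0.54, SE 0.12) rose. Of the interferon response genes, Iigp1 (0.66, SE 0.19) and Gbp3 (0.45, SE 0.13) rose while Oasl2 fell by 0.80 (SE 0.20), and that list was not called.

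Cell cycle genes had a median change of 0.28 in dKO against WT, with 26 of 29 positive and 0 passing adjusted over the list alone (camera adjusted p = 0.000349; adjusted p = 0.79 with an estimated correlation). Without dKO 2 the median was 0.09 and the call was lost (adjusted p = 0.389), as it was with array weights (0.0553), while without WT 3 or dKO 1 the median was 0.18 or 0.53 and called. Effector cytokine genes had a median of 0.20 (adjusted p = 0.025), and Ifng stood at 0.64 (SE 0.21) without passing. This call was lost with an estimated correlation (adjusted p = 0.79), without WT 1 (0.267) or dKO 2 (0.0699), without a filter (0.056), under the stricter filter (0.48), with only the groups compared (0.0701), with all 6 WT arrays pooled (0.202), with the 9 arrays of set 1 alone (0.0952), without both B cell arrays (0.337) and with the B cell mean or the Eif2s3y signal as a covariate (0.184 and 0.219). The fit with the replicate block, made on set 1 alone, lacked the effector cytokine call too (camera adjusted p = 0.0742). As set 1 alone lost it without the block (0.0952), this loss is not credited to the block. With the WT arrays of the other set camera lost this call and those of the cell cycle, activated/effector and chemokine receptor lists (adjusted p = 0.627 to 0.893). The B cell list, at -0.71 (adjusted p = 0.000196; adjusted p = 0.79 with an estimated correlation), had a median of 0.01 without WT 1 (adjusted p = 0.858), where camera called 3 lists, and of -1.065 or -1.064 without WT 2 or WT 3, both called. The remaining 22 lists were not called.

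**Figure D3:**
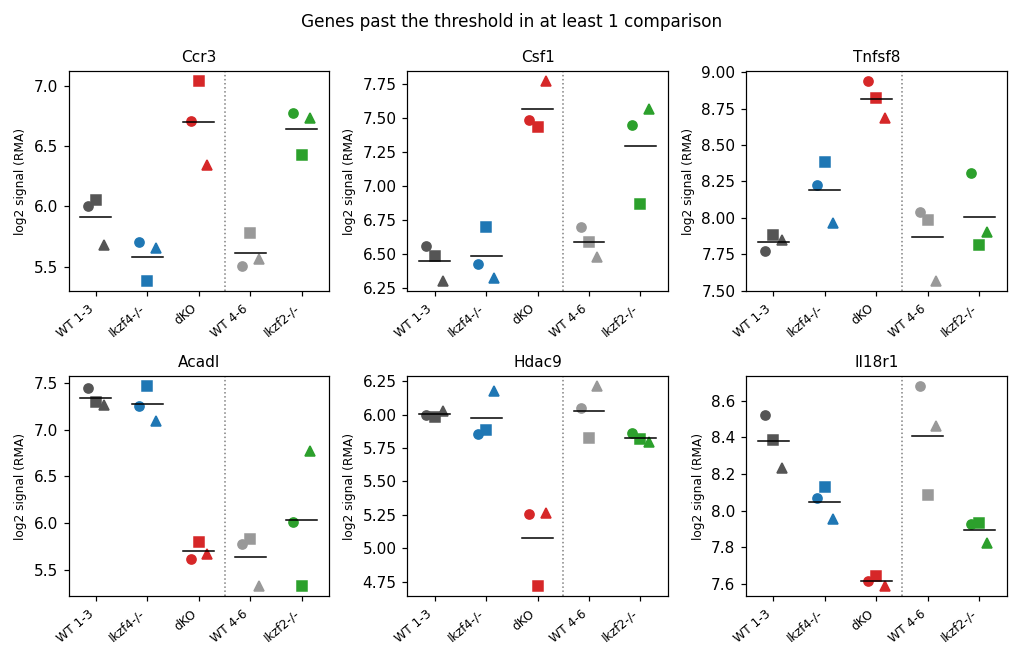
Log2 RMA signal per array of 6 genes past the limma threshold in at least 1 comparison, with a bar at the group mean and a dotted line between the separately normalized sets. Ccr3 and Csf1 are high in both dKO (means 6.70 and 7.56) and Ikzf2-/- (means 6.65 and 7.29), while Acadl is low in dKO (mean 5.70) and in both groups of set 2 (means 5.64 and 6.04).

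The added effect of losing Ikzf2 in cells lacking Ikzf4 was read from dKO against Ikzf4-/-. Ccr3 rose 2.18-fold (log2 1.12, SE 0.17) and Csf1 2.12-fold (1.08, SE 0.16), while Sidt1, a membrane protein gene of the SID1 family, fell by 0.58 (SE 0.09), each with an adjusted p of 0.0453. These were the 3 genes called. In the Ikzf2-/- arrays of set 2, which share no array with this comparison, the changes were 1.03 for Ccr3, 0.71 for Csf1 (SE 0.16, adjusted p = 0.0849) and -0.46 for Sidt1 (SE 0.09, adjusted p = 0.0700), of which Ccr3 passed. With the replicate number as a block, Ccr3, Csf1 and Sidt1 had adjusted p of 0.194, 0.163 and 0.191 in limma and were not called, while Acadl (-1.57, SE 0.09, adjusted p = 0.00547) and Iigp1 (1.00, SE 0.09, adjusted p = 0.0449) were. In the main fit of all arrays, without the block, Acadl had an adjusted p of 0.0504. The block was fitted to set 1 alone, and set 1 alone without the block gave 1 gene. The block and the omission of set 2 were therefore not told apart. Limma called 0 genes without a filter, when quantile-normalized again and with the Eif2s3y signal as a covariate, and array weights gave 21. Leaving out Ikzf2-/- 2 gave 11 genes, leaving out Ikzf2-/- 3 gave 2, leaving out dKO 1 or the array labelled dKO 3 gave 1, and leaving out any of the other 11 arrays gave 0.

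Camera called 8 lists between dKO and Ikzf4-/-, and none of these calls held in fry's test of one direction (adjusted p = 0.753 for each), while its test of either direction passed for the chemokine receptor and homing list alone (adjusted p = 0.027). Cell cycle genes had a median of 0.43, with 27 of 29 positive (adjusted p = 7.49e-13; adjusted p = 0.448 with an estimated correlation), and Mki67 (0.86, SE 0.32) and Rrm2 (0.84, SE 0.32) had the largest values, although 0 members passed adjusted over the list alone. Activated/effector Treg genes had a median of 0.36, with 4 of 22 risen adjusted over the list alone (adjusted p = 6.84e-11, and adjusted p = 0.448 with an estimated correlation): Ccr2 (1.39, SE 0.32), Cxcr3 (0.77, SE 0.19), Lag3 (0.74, SE 0.23) and the costimulatory receptor gene Icos (0.46, SE 0.15). Interferon response genes had a median of 0.12, with Iigp1 (1.00, SE 0.19) and Gbp3 (0.51, SE 0.13) risen adjusted over the list alone (camera adjusted p = 0.000281, and adjusted p = 0.531 with an estimated correlation). The chemokine receptor and homing list shares Ccr2 and Cxcr3 with the activated/effector list, so these results overlap. Chemokine receptor and homing genes (median 0.12, 3 of 22 risen adjusted over the list alone and 1 over all genes, adjusted p = 0.00198, and adjusted p = 0.531 with an estimated correlation) and heat shock genes (0.15, 9 of 9 positive, adjusted p = 0.00367, and adjusted p = 0.448 with an estimated correlation) were higher. So were effector cytokine genes (0.15, adjusted p = 0.0211, and adjusted p = 0.448 with an estimated correlation), among which Ifng, the interferon gamma gene, rose adjusted over the list alone (0.90, SE 0.21). Cholesterol synthesis genes (-0.13, 14 of 15 negative, adjusted p = 0.00169, and adjusted p = 0.448 with an estimated correlation) and resting/central T cell genes (-0.12, 10 of 14 negative, adjusted p = 0.0408, and adjusted p = 0.531 with an estimated correlation) were lower. Socs2 (0.47, SE 0.12), Socs3 (0.42, SE 0.13) and Slamf6 (0.36, SE 0.09) also rose adjusted over their lists alone.

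With the replicate block, fitted to set 1 alone, the effector cytokine list was no longer called (adjusted p = 0.111). Nor was it with set 1 alone and no block (0.132), so this loss is not credited to the block. It was also lost with only the groups compared (0.122), without a filter (0.0526), under the stricter filter (0.754) and with the Eif2s3y covariate (0.113). The plasma cell list, with a median of 0.26, was called with the block (adjusted p = 0.0123) and not in the main fit (0.0892). The B cell list mean was level here (median change -0.05), and the 6 neutrophil genes were all positive (median 0.41) without a call. The list of 6 genes higher in conventional CD4 cells than in Treg cells had its highest mean of set 1 in dKO 2 (9.16, against 8.16 to 8.55), the array with the highest cell cycle mean, and camera did not call it (adjusted p = 0.878). The cell cycle and activated/effector calls held without each array in turn, with medians of 0.29 to 0.67 and 0.29 to 0.50. Without Ikzf4-/- 1, 4 lists were called, and the chemokine receptor, effector cytokine, interferon and resting/central lists were not (adjusted p = 0.0701, 0.171, 0.0701 and 0.171). The resting/central call was also lost without WT 1, WT 3, Ikzf4-/- 3 or the array labelled dKO 3 (adjusted p = 0.0528 to 0.726), with only the groups compared (0.0556), without both B cell arrays (0.0553), with all 6 WT arrays pooled (0.122) and with the Eif2s3y covariate (0.0728). The heat shock call was lost without Ikzf4-/- 3 (0.106) or dKO 2 (0.0527), the effector cytokine call without dKO 2 (0.0765), and the cholesterol call without the array labelled dKO 3 (0.287). Among calls that held, the effector cytokine median was 0.094 without Ikzf4-/- 2, 0.22 without dKO 1 and 0.24 without the array labelled dKO 3, the interferon median 0.072 and the cell cycle median 0.67 without dKO 1, and the chemokine receptor median 0.19 without the array labelled dKO 3. Without Ikzf4-/- 2, camera called 11 lists.

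The added effect of losing Ikzf4 in cells lacking Ikzf2 was the difference between the dKO and Ikzf2-/- changes. Limma called 0 genes (smallest adjusted p = 0.616), with 789 at an unadjusted p under 0.05. The smallest p belonged to Acadl (-2.03, SE 0.37), Oasl2 (-1.43, SE 0.28), Islr (-0.95, SE 0.19), Hddc3 (0.92, SE 0.19) and Srek1ip1 (-0.53, SE 0.11). Oasl2 and Rplp0 (-0.51, SE 0.12) fell adjusted over their lists alone. The B cell, neutrophil, oxidative phosphorylation and cell cycle lists were lower in camera, with median differences of -1.66, -2.06, -0.16 and -0.28 (adjusted p = 2.48e-06, 0.00654, 0.0179 and 0.0235). With an estimated correlation the smallest adjusted p was 0.945, and without WT 1 and Ikzf2-/- 3, or with the B cell mean as a covariate, camera called 0 lists. For the B cell list the loss with the covariate was fixed in advance, as the covariate is its own mean. The cell cycle call was lost without WT 2, WT 6, dKO 1 or Ikzf2-/- 3 (adjusted p = 0.0981 to 0.758), and the oxidative phosphorylation call without WT 1, WT 6 or Ikzf2-/- 3 (0.0569 to 0.107). The former was also lost under the stricter filter (0.262) and the latter when quantile-normalized again (0.175), and both with all 6 WT arrays pooled (0.0898 and 0.775) and with the replicate block, which here crosses the sets (0.0723 and 0.524). The B cell and neutrophil medians were -0.91 and -1.24 without WT 1 and -0.97 and -1.21 without Ikzf2-/- 3, and the cell cycle median was -0.46 without dKO 2 and -0.51 without Ikzf2-/- 2, all of them called. Leaving out Ikzf2-/- 1, 2 or 3 gave 2, 1 and 2 genes.

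Whether the single-knockout changes add up to that of dKO was tested as dKO minus Ikzf4-/- minus Ikzf2-/- plus WT, within sets. Limma called 0 genes (smallest adjusted p = 0.767), with 682 at an unadjusted p under 0.05. The smallest p belonged to Acadl (-1.97, SE 0.37), Mis18a (-0.91, SE 0.20), Lancl1 (-0.64, SE 0.15), Ppdpf (-0.78, SE 0.18) and Mrps34 (-0.58, SE 0.14). Interferon response genes were above the sum (median 0.17, 20 of 22 positive, adjusted p = 0.0236), and oxidative phosphorylation (-0.17) and B cell genes (-0.87) were below it (both adjusted p = 0.0107). With an estimated correlation the smallest adjusted p was 0.978. Without Ikzf2-/- 1, 2 or 3, limma called 4, 1 and 1 genes. Without Ikzf4-/- 2 or WT 6, camera called 7 and 6 lists, and without Ikzf2-/- 3 the B cell and oxidative phosphorylation calls were lost (adjusted p = 0.475 and 0.0968). The oxidative phosphorylation call was also lost without both B cell arrays (median -0.106, adjusted p = 0.0821), with the B cell covariate (-0.109, 0.106), when quantile-normalized again (-0.134, 0.112), with all 6 WT arrays pooled (0.57) and with the replicate block, which here crosses the sets (0.704). The B cell call was also lost under the stricter filter (0.357). Its loss with that covariate (0.898) was fixed in advance, as the covariate is this list's own mean. The interferon call was lost without WT 4, Ikzf4-/- 1, dKO 1 or Ikzf2-/- 1 (0.159 to 0.721), with all 6 WT arrays pooled (0.152) and with the replicate block (0.885). Among calls that held, the interferon median was 0.37 without Ikzf2-/- 3, the B cell median -1.455 without Ikzf2-/- 2 and the oxidative phosphorylation median -0.099 without WT 6.

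Changes were compared across all 10834 genes, which are not independent replicates. Ikzf2-/- vs WT and dKO vs WT, with no shared array, correlated weakly (Pearson r = 0.142, Spearman rho = 0.196), and 33 of 200 within-set splits of the arrays gave an r as high (one-sided exact permutation p = 0.165 before and after Benjamini-Hochberg). This r was 0.305, 0.068, 0.008 and 0.093 without WT 1, WT 2, WT 3 and WT 6, 0.227 without both B cell arrays and 0.021 with the B cell covariate. With WT pooled or of the other set it was -0.317 and -0.735. There the set difference enters both changes with opposite signs, which by itself lowers r. Ikzf2-/- vs WT and dKO vs Ikzf4-/-, also without shared arrays, correlated at r = 0.306 and rho = 0.227. This r was 0.203 without Ikzf4-/- 3 and 0.152 with the replicate block, which for Ikzf2-/- vs WT crosses the sets, and the permutation was not repeated for these. With the paired dKO and Ikzf4-/- arrays exchanged only within their pairs, the real split alone of 80 reached that r, the highest other being 0.276 (one-sided exact permutation p = 0.0125, the smallest that these splits can give, and 0.025 after Benjamini-Hochberg over the 2 permutation tests). At an unadjusted p under 0.05, 72 genes were higher in both, against 21.5 for independent lists, and 32 were lower in both, against 9.78. Both comparisons called 1 gene, Ccr3. This pair was added after the data were seen, as the last of 3 correlations computed.

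Ikzf4-/- vs WT and dKO vs WT share WT 1 to 3. They correlated at r = 0.527 (rho = 0.465), against a mean of 0.496 (range 0.362 to 0.630) in 100 simulations of unchanged groups sharing 3 controls. The simulated arrays were independent, without the pairing by replicate number. With WT pooled or of the other set r was 0.808 and 0.936. There both changes contain the same set difference, which by itself raises r. With WT 1 to 3 the covariance was 0.0123, against 0.0105 simulated, a difference of 0.00179. The same sign was shared by 66.6% of genes, against 66.6% simulated. At an unadjusted p under 0.05, 47 genes were higher in both, against 3.06 for independent lists, and 34 were lower in both, against 2.03. Independent lists are not the no-change value here, because the controls are shared. The 3 controls cannot be split and no overlap was simulated, so how much of this excess comes from them, part or all, is not known.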

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

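Of the tests here, those of other splits of the arrays (apart from the count by pairs) and of an independent set of B cell genes were chosen before their results were seen, and the others only after.

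Array WT 1 had a B cell list mean of 6.51, apart from the other WT arrays (4.53 to 5.22), with a gap of 0.653 of the whole range. WT 3 had a sex-linked list mean of 6.36, against 4.92 to 5.03, with a gap of 0.924 of the range. A total of 39 values were tested in this way over the 6 WT arrays, and chance alone marks about 1 in 20. The change in dKO differed from that in Ikzf2-/-, by camera on the difference itself, for the B cell (-1.66), neutrophil (-2.06), cell cycle (-0.28) and oxidative phosphorylation lists (-0.16). These calls were lost with an estimated correlation (adjusted p = 0.945 for each), and camera called 0 lists without WT 1 and Ikzf2-/- 3. The sum of the single-knockout changes differed from the dKO change for the B cell (-0.87), interferon response (0.17) and oxidative phosphorylation lists (-0.17). These calls were lost with an estimated correlation (adjusted p = 0.978 for each) and in fry's test of one direction (0.995), and 76 of 100 splits of the arrays called as many lists.

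The first pattern is the high B cell list in WT 1 and Ikzf2-/- 3. The sort for CD4+CD25+ cells should remove B cells, yet Cd74, abundant in B cells, read 9.45 and 9.85 in these arrays, against 6.91 to 8.48 in the others. Of 20 further B cell genes, 12 of which were also above the signal filter in Ikzf4-/- and dKO arrays, 19 were higher in WT 1 and 20 in Ikzf2-/- 3 than the mean of the other arrays of the group, with medians of 1.54 and 1.65. Against loss of Ikzf2, the list mean of Ikzf2-/- 1 and 2 together was only 0.18 above that of WT 4 to 6. Singly they read 5.61 and 4.94, so Ikzf2-/- 1 lay above WT 4 to 6 (5.03 to 5.22). Against loss of Ikzf4, the median change of the list in Ikzf4-/- without WT 1 was 0.011. RNA from B cells in these 2 arrays may therefore be the source, as a hypothesis. The neutrophil list (7.71 and 9.58) and the macrophage and dendritic cell list (7.86 and 8.07) were also highest of their sets there, so other cells stay open.

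The second pattern is the cell cycle and activated/effector lists, higher in dKO than in Ikzf4-/-, with 2 of the 3 dKO arrays above all Ikzf4-/- arrays for each list. By replicate number, each dKO array lay above its Ikzf4-/- partner for both lists. The cell cycle means were 6.722, 7.389 and 7.122, against 6.468, 6.956 and 6.529. The activated/effector means were 7.934, 8.174 and 7.989, against 7.395, 7.98 and 7.407. The B cell list mean was level over the dKO and Ikzf4-/- arrays (4.50 to 4.66), which argues against B cell RNA as the whole cause. With so level a covariate the list medians could hardly change, so the share kept (at least 101%) is no test. With the Eif2s3y signal as a covariate at least 93.5% of each list median was kept, which does not settle sex. The dKO arrays above all Ikzf4-/- arrays were dKO 2 and the array labelled dKO 3, both with the Y-linked signal. Without that signal, dKO 1 read 6.72 and 7.93, below Ikzf4-/- 2 (6.96 and 7.98). The cell cycle mean was higher in arrays with the signal in dKO and lower in WT, which a single slope cannot follow. Partners numbered 1 and 3 had the same Y-linked state, and dKO was higher there for both lists. If loss of Ikzf2 were the cause, all 3 Ikzf2-/- arrays of set 2 might be expected above all WT arrays. For the cell cycle list 3 were, and for the activated/effector list 2. The exception was Ikzf2-/- 2 (7.21, against 7.04 to 7.48 in WT 4 to 6), the array with the lowest weight (0.126). Genes higher in conventional CD4 than in Treg cells had a median of 0.11 in dKO against Ikzf4-/- and were not called (camera adjusted p = 0.878), with the highest mean of set 1 in dKO 2 (9.16) and the lowest in the array labelled dKO 3 (8.16), whose cell cycle mean of 7.12 also lay above all Ikzf4-/- arrays. Loss of Ikzf2 therefore stays open, as does a mixture with conventional CD4 cells, since 1 array and 6 genes do not settle it.

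The third pattern is Acadl and Lancl1, lower in dKO than in Ikzf4-/- by log2 values of -1.57 and -0.64 (adjusted p = 0.0504 for both in limma). They lie 2 and 1 tested genes from Ikzf2 on chromosome 1. Lancl1 stood at -0.002 in Ikzf2-/- (95% interval -0.22 to 0.22), with no fall after loss of Ikzf2 alone. Acadl stood at 0.40 there (-0.16 to 0.95), but WT 4 to 6 lay only 0.68 above the signal filter, so for Acadl this cannot be told apart. Acadl and Lancl1 were also lower in WT 4 to 6 than in WT 1 to 3, by -1.69 and -1.04 (adjusted p = 0.000121 and 6.26e-06 in limma). The median over all genes was -0.39, and these values are set across separate normalizations. If WT 4 to 6 already had the low level, a fall in Ikzf2-/- might not show, so Lancl1 does not settle loss of Ikzf2 alone either. A list of neighbours of Ikzf2, fixed before the data were examined, holds neither gene and had 3 measured members. It was not called in dKO against Ikzf4-/- (median 0.10, 2 of 3 positive, camera adjusted p = 0.314). So few genes do not settle it, and sequence linked to the targeted locus stays open for Acadl and Lancl1, with no further test made.

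Other splits of the arrays were counted for each total. For comparisons of 3 arrays with 3 there are 10 splits, too few for a share under 0.05. The real split called 7 genes in Ikzf2-/- vs WT (1 of the 10 splits as many, highest other 4), 0 in Ikzf4-/- vs WT (10, highest other 0), 7 in dKO vs WT (1, highest other 0), 3 in dKO vs Ikzf4-/- (1, highest other 0) and 6950 between the WT sets (1, highest other 0). It called 5, 4, 5 and 8 lists in the first 4 of these; 5, 7, 7 and 2 of the 10 splits called as many, and the highest others were 9, 8, 12 and 8. For dKO vs Ikzf2-/-, 100 of 100 splits called at least the real 0 genes (highest other 17) and 64 at least the real 4 lists (highest other 11). For the sum of the single knockouts, 100 of 100 splits called at least the real 0 genes (highest other 24) and 76 at least the real 3 lists (highest other 11). Chance was not excluded for these. Splits calling up to 24 genes, against the real 0, may reflect a structure among the arrays other than genotype or the wider spread of the Ikzf2-/- arrays under a shared estimate, which were not told apart by a test. Where the numbers pair the arrays, 4 of the 10 splits part all 3 pairs and the other 6 part 1. Among those 4, the highest other was 0 genes and 6 lists in Ikzf4-/- vs WT (real 0 and 4) and 0 genes and 8 lists in dKO vs Ikzf4-/- (real 3 and 8); the other 6 reached 0 genes and 8 lists, and 0 genes and 5 lists.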

How the results depend on the processing

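The arrays left out for B cell markers, both covariates, fry's test of either direction, the fit of set 1 alone and the correlation of Ikzf2-/- vs WT with dKO vs Ikzf4-/- were chosen only after the data were seen. The B cell covariate is the mean of the B cell list itself, so it takes out that list's own change by construction. Fits that cross the sets compare arrays normalized separately, and their large counts follow the difference between sets. Correlations of changes from WT that are pooled or of the other set also contain that difference. For all other changes the cause was not tested. Signal over background limits dim genes, whose changes RMA compresses. Named genes kept their direction and side of the threshold in 1424 cases, were no longer past it in 116, newly past it in 75 and reversed in 19. Lists did so in 335, 115, 0 and 9, and with each array left out in 395, 39, 0 and 1, and genes in 1554, 212, 19 and 0. A change of sign where neither value passed was counted as the same.

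In Ikzf2-/- vs WT, limma called 0 genes with all 6 WT arrays pooled and 0 with only the groups compared. It called 2 without a filter, 23 when quantile-normalized again, 66 with array weights, 3 without the B cell arrays, and 0 with the B cell mean or with Eif2s3y as covariate. With the WT arrays of the other set it called 6493, and with the replicate block, which there crosses the sets, 5974. In Ikzf4-/- vs WT the other set gave 7170. In dKO vs WT the counts were 4 (pooled WT), 7205 (other set), 1 (groups compared only), 0 (no filter), 2 (quantile), 4 (equal medians), 22 (array weights), 1 (replicate block), 2 (without the B cell arrays), 3 (B cell covariate) and 0 (Eif2s3y covariate). In dKO vs Ikzf4-/- they were 0 (pooled WT), 1 (groups compared only), 0 (no filter), 5 (stricter filter), 0 (quantile), 7 (mean of probe sets), 7 (trend and robust), 21 (array weights), 0 (Eif2s3y covariate) and 1 (set 1 alone). In dKO vs Ikzf2-/- they were 3669 (pooled WT), 1 (array weights), 6256 (replicate block) and 2 (without the B cell arrays). For the sum of the single knockouts they were 1 (array weights), 3468 (replicate block) and 1 (without the B cell arrays). The difference between WT sets was 3935 genes when quantile-normalized again (1234 higher, 2701 lower) and 3687 at equal medians (2360 higher, 1327 lower).

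With an estimated correlation and with fry's test of one direction, 0 lists were called in all 6 comparisons. Fry's test of either direction passed for 4 lists in Ikzf2-/- vs WT, 1 in dKO vs WT, 1 in dKO vs Ikzf4-/- and 0 in the other 3 comparisons. Ikzf2-/- vs WT had 3 lists under the stricter filter, 11 with array weights and 2 with the B cell covariate. Ikzf4-/- vs WT had 8 with pooled WT, 7 with the other set, 7 without a filter and 1 with the B cell covariate. dKO vs Ikzf2-/- had 0 without the B cell arrays and 0 with the B cell covariate.

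Over 836 values of called lists under these settings (apart from the estimated correlation and fry) and with each array left out, 23 medians had another sign than in the report, 17 differed in sign from camera's direction, and camera's direction turned in 10. It turned for oxidative phosphorylation, at -0.26 in Ikzf2-/- vs WT (other set, replicate block), 0.33 in dKO vs Ikzf2-/- (pooled WT, replicate block) and 0.30 for the sum of the single knockouts (replicate block). It also turned for the B cell list, at -0.033 in Ikzf2-/- vs WT with the B cell covariate and at 0.011 in Ikzf4-/- vs WT without WT 1 or without both B cell arrays; with each array left out that list ranged from -0.96 to 0.011. It turned without a change in the sign of the median for the activated/effector list in dKO vs WT with the other set (0.69) and the B cell list for the sum of the single knockouts with the B cell covariate (-0.041). The median changed sign and camera's direction did not in the other cases: oxidative phosphorylation stood at -0.058 in Ikzf2-/- vs WT and 0.099 for the sum of the single knockouts (pooled WT). The cell cycle list stood at -0.009 in Ikzf2-/- vs WT (other set, replicate block), 0.084 and 0.36 in Ikzf4-/- vs WT (pooled WT, other set), and 0.195 (pooled WT, replicate block) and 0.063 (B cell covariate) in dKO vs Ikzf2-/-. The interferon list stood at 0.007 and 0.22 in Ikzf4-/- vs WT (pooled WT, other set), the B cell list at 0.014 (without WT 1, without both B cell arrays) and 0.038 (B cell covariate) in dKO vs WT, and the neutrophil list at 0.042 in dKO vs Ikzf2-/- (B cell covariate). Genes reversed in Ikzf2-/- vs WT with the other set and the replicate block were Map6 (-0.28), Prg4 (-0.17), Ccnd2 (-0.25), Ndufb8 (-0.27), Rplp0 (-0.25) and Ikzf1 (-0.36), and with the other set alone Ikzf3 (-0.35) and Ctla4 (-0.26). In dKO vs WT with the other set Acadl stood at 0.055 and Oasl2 at 0.47. Ikzf3 in dKO vs Ikzf2-/- stood at 0.64 (pooled WT, replicate block) and Mrps34 at 0.85 for the sum of the single knockouts (replicate block). The targets passed the threshold only across sets or with an array left out: Ikzf2 at -1.18 in Ikzf2-/- (other set, replicate block), and Ikzf4 at 0.32 in Ikzf4-/- and 0.27 in dKO (other set).

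The correlation of Ikzf2-/- vs WT with dKO vs WT was -0.317 with pooled WT, -0.735 with the other set, 0.227 without the B cell arrays and 0.021 with the B cell covariate. That of Ikzf4-/- vs WT with dKO vs WT was 0.808, 0.936, 0.622 and 0.616. That of Ikzf2-/- vs WT with dKO vs Ikzf4-/- was 0.248 with pooled WT, 0.152 with the replicate block, 0.209 without the B cell arrays, 0.212 with the B cell covariate and 0.362 with Eif2s3y. Where the numbers pair the arrays, the block was fitted to set 1 alone. That fit differed from the main one in the calls over all genes and of lists given with dKO vs Ikzf4-/-. No other of these calls differed.

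Leaving out each array in turn gave 0 to 404 genes in Ikzf2-/- vs WT, 0 to 1 in Ikzf4-/- vs WT, 0 to 9 in dKO vs WT, 0 to 11 in dKO vs Ikzf4-/-, 0 to 2 in dKO vs Ikzf2-/- and 0 to 4 for the sum of the single knockouts. List counts were 3 to 7, 2 to 5, 3 to 6, 4 to 11, 3 to 5 and 2 to 7. The difference between WT sets was 5894 to 7628 genes. The correlations were 0.008 to 0.305, 0.422 to 0.655 and 0.203 to 0.345, in the order above. Ikzf2 ranged from -1.15 to -0.70 in Ikzf2-/-, -0.08 to 0.10 in Ikzf4-/- and -0.52 to -0.28 in dKO, and Ikzf4 from 0.03 to 0.20, 0.14 to 0.25 and 0.08 to 0.20.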

Other observations

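These values were singled out only after they were seen. Of 5 plasma cell genes, 2 were higher and 1 lower in WT 4 to 6 than in WT 1 to 3 past limma's threshold over all genes: Jchain, the joining chain of secreted antibodies (log2 2.62, SE 0.66), Igha (2.21, SE 0.71) and the transcription factor gene Xbp1 (-0.80, SE 0.15). The list's median was 0.28, and its camera call (adjusted p = 0.0311) was lost with an estimated correlation (adjusted p = 0.866) and when quantile-normalized again (0.328) or at equal array medians (0.306). Of 23 genes of the immediate early response to the T cell receptor, 20 were lower in WT 4 to 6 past that threshold, among them Jun (-1.88, SE 0.27), Nr4a1 (-1.15, SE 0.20) and Nr4a3 (-0.92, SE 0.12). The list's median was -0.59, against -0.39 over all genes, and camera did not call it (adjusted p = 0.0817, and 0.866 with an estimated correlation), while fry's test of one direction, which does not compare a list with other genes, gave an adjusted p of 2.59e-05 (0.46 for the plasma cell list). At equal array medians, where the median over all genes was 0.052, these 3 genes stood at -1.44, -0.71 and -0.48, and the list at -0.15 (camera adjusted p = 0.0316). Quantile-normalized again, the list stood at -0.26 and was not called (adjusted p = 0.149). Since the sets were normalized separately, these levels are set across 2 normalizations.

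Of 6974 probe sets without a single symbol, limma called 0 in each of the 6 comparisons. In Ikzf2-/- vs WT 923 had an unadjusted p under 0.05, with a smallest adjusted p of 0.054. In dKO vs Ikzf4-/- 219 did, with a smallest adjusted p of 0.416.

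The array dKO 2 carried both Xist (7.25) and Eif2s3y (7.94), while each of the other 14 arrays carried 1 of them near 8 to 10 and the other near 3 to 4. No test of its origin was made.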
